A study of Mus musculus with 6 samples.

How the data were processed

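Liver RNA of 3 wild-type and 3 PiZ mice, 6 weeks old and on a C57BL/6 background, was measured on one-colour Affymetrix arrays. Per the labels' protocols, total RNA was column-purified and turned into biotinylated cRNA by in vitro transcription. The deposited values are log2 intensities per probe set, and the authors made them with the affy package and RMA, per the submitters' processing notes. RMA corrects the background, makes the distributions of all arrays alike by quantiles, and summarises the probes of a probe set, so a change shared by most genes would be removed. Versions of these tools, the chip definition and any filter are not given in the sources used here. The log2 scale was taken from the values, which lie between 2.3 and 14.98. All 6 value columns were matched to samples and no other sample column was present. The labels call the samples biological replicates, so p-values rest on the spread between these mice. In PiZ that spread also holds a difference in RNA quality between arrays, given below.

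Each array held 22690 probe sets, of which 64 were controls. A table of the platform's annotation named exactly 1 gene for 20380 probe sets, several genes for 691 and none for 1555. The last 2 kinds were not named here. Entrez identifiers of 20351 of the 20380 probe sets were found in the mouse reference table, and 0 symbols needed an update. These probe sets named 12393 genes, 4956 of them by more than 1 probe set. Each gene was represented by the probe set with the highest mean over all arrays. Of 1392 changed genes with several probe sets, 949 had all of them in one direction, and 23 genes had probe sets called in opposite directions. No build was named by the files, so no coordinates are given. The files held no detection calls, so a dim gene cannot be told from background. The lower quartile of probe set values was 4.28, 4.32 and 4.28 in wild-type and 4.35 in PiZ replicate 1. It was 4.46 and 4.45 in PiZ replicates 2 and 3. Changes of dim genes are thus uncertain in size, and small rises of dim genes in PiZ need care.

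Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate, two-sided), with Benjamini-Hochberg adjustment over the 12393 genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 37 lists with at least 5 measured members (reference and sex chromosome genes left out). Counts adjusted over the list alone are given beside those over all genes. The fry test asks whether the genes of a list move one way on balance, without comparing them with other genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The 39 lists were written from general knowledge before the data were examined, and those on HNF4A, liver transcription factors and zonation follow the study's known interest. The lists overlap: Lcn2, Gstm3, Slco1a1, Atf3 and Cdkn1a, for example, belong to more than 1.

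Named genes followed a rule fixed at the same time. They were the 12 largest rises and 12 largest falls among changed genes with non-overlapping groups and a proper gene name, up to 4 changed members of each list by size (or the 2 with the smallest p where none passed), and a fixed set that included Hnf4a, the Serpina1 genes, Glul, Cyp2e1, Cyp7a1, Hspa5, Xbp1, Arntl and the sex chromosome genes. Of 158 named genes 143 changed.

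The fit was tested on simulated data for PiZ against wild-type, 3 arrays against 3 with 12393 genes and 200 of them changed. It called 70% of the genes changed by 1 on the log2 scale and 97% of those changed by 2. Among 174 calls 7 were of unchanged genes, and 0 changed genes had the wrong sign. With nothing changed 0 lists were called, and a list lowered by 0.5 was called lower. The simulated genes varied independently of each other and with the same spread in both groups. This therefore does not check the list test on genes that vary together, nor the gene calls where PiZ arrays spread more than wild-type.

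Alternatives fixed in advance changed the choice of probe sets, the filter on dim genes, the scaling of arrays (cyclic loess, a further quantile normalization, centring on reference genes), the variance model, array weights, the set test and the threshold, used the replicate number as a block, and left out each array in turn. After the data were seen, 3 more were added: PiZ replicate 1 alone against wild-type, the mean 3′ to 5′ difference of the control transcripts as a covariate, and camera with an estimated correlation without PiZ replicate 1. Pearson correlations between arrays and principal components described the arrays without a test.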

Results

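Gene expression was measured in the livers of 3 PiZ and 3 wild-type mice at 6 weeks of age, with 1 array per biological replicate. PiZ mice carry a human transgene for the Z form of alpha-1 antitrypsin. This mutant serpin (a protease inhibitor) misfolds and collects in the endoplasmic reticulum (ER) of hepatocytes, and the mice serve as a model of the liver disease of alpha-1 antitrypsin deficiency. The values were log2 intensities from a one-colour Affymetrix array, on which a gene is read by one or more sets of short probes (probe sets). In all, 12393 genes had a probe set of their own. The single comparison set PiZ against wild-type liver. It asks which liver genes differ when the mutant protein is made, and in particular what happens to genes that depend on HNF4A, a transcription factor of mature hepatocytes, and to genes expressed at one end of the liver lobule. Fold changes below are PiZ minus wild-type on the log2 scale from limma, with standard errors (SE), and n = 3 per group throughout. The number of arrays limits the precision.

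The arrays separated by group, and PiZ replicate 1 stood apart from the other PiZ arrays. Array medians lay between 6.13 and 6.19. Across genes, the wild-type arrays correlated with each other at 0.996 to 0.997. PiZ replicates 2 and 3 correlated at 0.993 with each other and at 0.962 to 0.969 with wild-type, and PiZ replicate 1 at 0.98 to 0.981 with wild-type. The first principal component held 73.0% of the variance, with PiZ replicate 1 at 9.86, replicates 2 and 3 at 41.8 and 40.0, and wild-type at -32.7, -26.8 and -32.2. RNA quality differed as well. The array reads the 3′ and the 5′ end of the control transcripts Gapdh and beta-actin, and a large difference between the ends is a known sign of shortened RNA. For Gapdh this log2 difference was 1.49, 2.06 and 1.65 in wild-type, 1.99 in PiZ replicate 1, and 4.39 and 4.01 in PiZ replicates 2 and 3. For beta-actin the values were 2.90, 3.34 and 2.95 in wild-type, 3.02 in PiZ replicate 1, and 4.89 and 4.66 in PiZ replicates 2 and 3. The added hybridization controls also read 1.08 and 0.999 above the wild-type mean in PiZ replicates 2 and 3, against 0.20 in PiZ replicate 1. For that reason the median change of each gene list is given for PiZ replicate 1 and for PiZ replicates 2 and 3 apart.

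**Figure D1:**
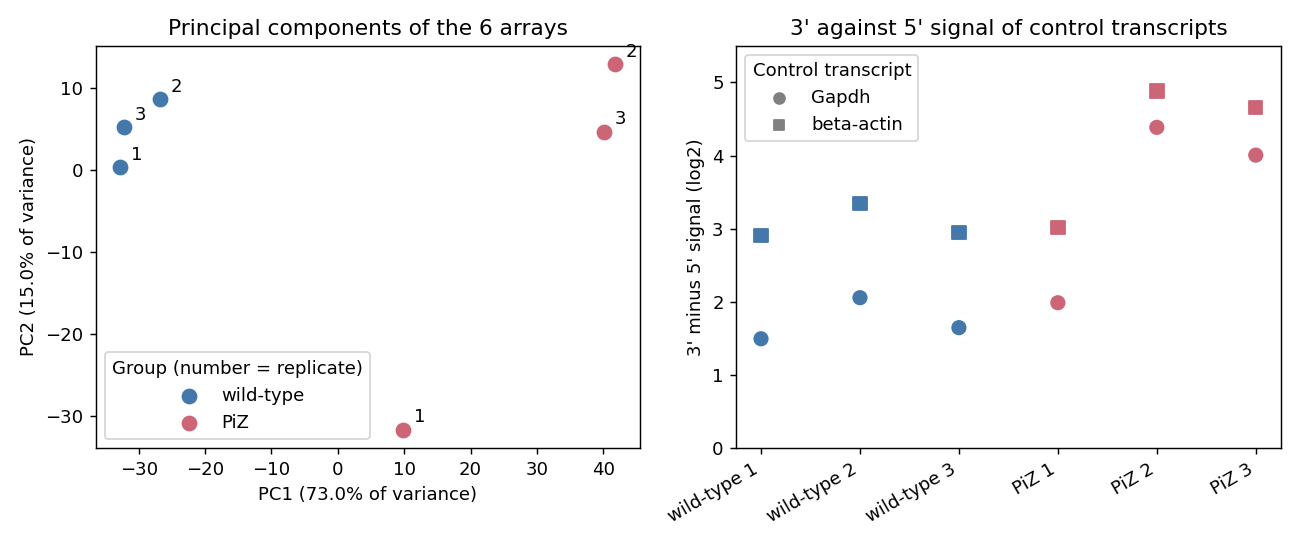
Left, the 6 arrays on the first 2 principal components of 12393 genes, with the percent of variance on each axis and the replicate number beside each point. Right, the log2 difference between the 3′ and 5′ signal of Gapdh (circles) and beta-actin (squares) in each array, where PiZ replicates 2 and 3 lie between 4.01 and 4.89 and the other 4 arrays between 1.49 and 3.34.

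The measured mouse alpha-1 antitrypsin genes did not pass the test, and the transgene was not analysed here, since no probe set was named for the human gene. Serpina1b, a mouse alpha-1 antitrypsin gene, read 14.65 ± 0.0095 (SD) in wild-type and 14.61 ± 0.004 in PiZ, a difference of -0.04 (SE 0.10, limma adjusted p = 0.8) that turned to 0.08 after cyclic loess and 0.07 after a further quantile normalization. Serpina1c differed by -0.25 (SE 0.10, adjusted p = 0.0995). Both lie close to the top of the array's range, where arrays compress differences, and the copies of this family are nearly identical in sequence. Serpina1a, Serpina1d and Serpina1e were not named by a single-gene probe set here. Of 4 measured sex chromosome genes, the Y-linked Kdm5d fell by 0.88 (SE 0.14, adjusted p = 0.00645), although its other 2 probe sets read 0.15 and -0.00013. Y-linked Eif2s3y (-0.23, SE 0.17) and Uty (-0.07, SE 0.11) and X-linked Xist (0.27, SE 0.18) did not pass, and 1 of the 4 fell when adjusted over the list alone. This list had a median of -0.15 and was too small to test as a set.

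Atf3, Ddit3, Trib3 and Asns, members of the unfolded protein response list, were among the 12 largest rises taken by the naming rule. Atf3 and Ddit3 (also called Chop), transcription factors of the response to misfolded protein and amino acid shortage, rose by 5.28 (SE 0.30) and 3.70 (SE 0.14). Nupr1, a stress-induced chromatin protein, rose by 4.90 (SE 0.17), Ddit4, an inhibitor of mTORC1, by 4.34 (SE 0.24), Trib3, a pseudokinase induced through Ddit3, by 4.13 (SE 0.21), and asparagine synthetase Asns by 3.70 (SE 0.24). The fetal liver protein gene Afp rose by 4.57 (SE 0.17), the carbonyl reductase Cbr3 by 5.19 (SE 0.26), the noncoding RNA Snhg11 by 5.64 (SE 0.36), the matrix protein gene Tinag by 4.26 (SE 0.20), the trypsin inhibitor Spink1 by 3.81 (SE 0.39) and Bhlha15 (Mist1), a factor of secretory cells, by 3.65 (SE 0.13). Their limma adjusted p ran from 1.36e-05 (Afp, Nupr1, Ddit3, Bhlha15) to 0.00128 (Spink1). The probe sets of Afp differed widely, from 0.13 to 4.57, and those of Bhlha15 from 0.53 to 3.65.

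Hsd3b5 and Ugt2b38 led the 12 largest falls taken by the naming rule. Hsd3b5, a steroid dehydrogenase of male liver, fell by 5.03 (SE 0.19), from 12.43 ± 0.16 (SD) to 7.40 ± 0.36, and the glucuronosyltransferase Ugt2b38 fell by 4.37 (SE 0.12, adjusted p = 9.71e-06). The lectin-like gene Clec2h fell by 3.70 (SE 0.56), and so did the forkhead factor Foxq1 (-2.89, SE 0.35), the hepatocyte homeobox factor Hhex (-2.82, SE 0.27) and Klf10 (-2.61, SE 0.25). Socs2, an inhibitor and target of growth hormone signalling, fell by 2.58 (SE 0.52), and the clock output factor Dbp (-2.54, SE 0.57), Serpina12 or vaspin (-2.53, SE 0.25), Phlda1 (-2.74, SE 0.30) and Cnmd (-2.54, SE 0.27) fell as well. The adenylate kinase Ak4 fell by 2.62 (SE 0.32) in its brightest probe set, but its 4 probe sets ran from -3.48 to 0.51.

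**Figure D2:**
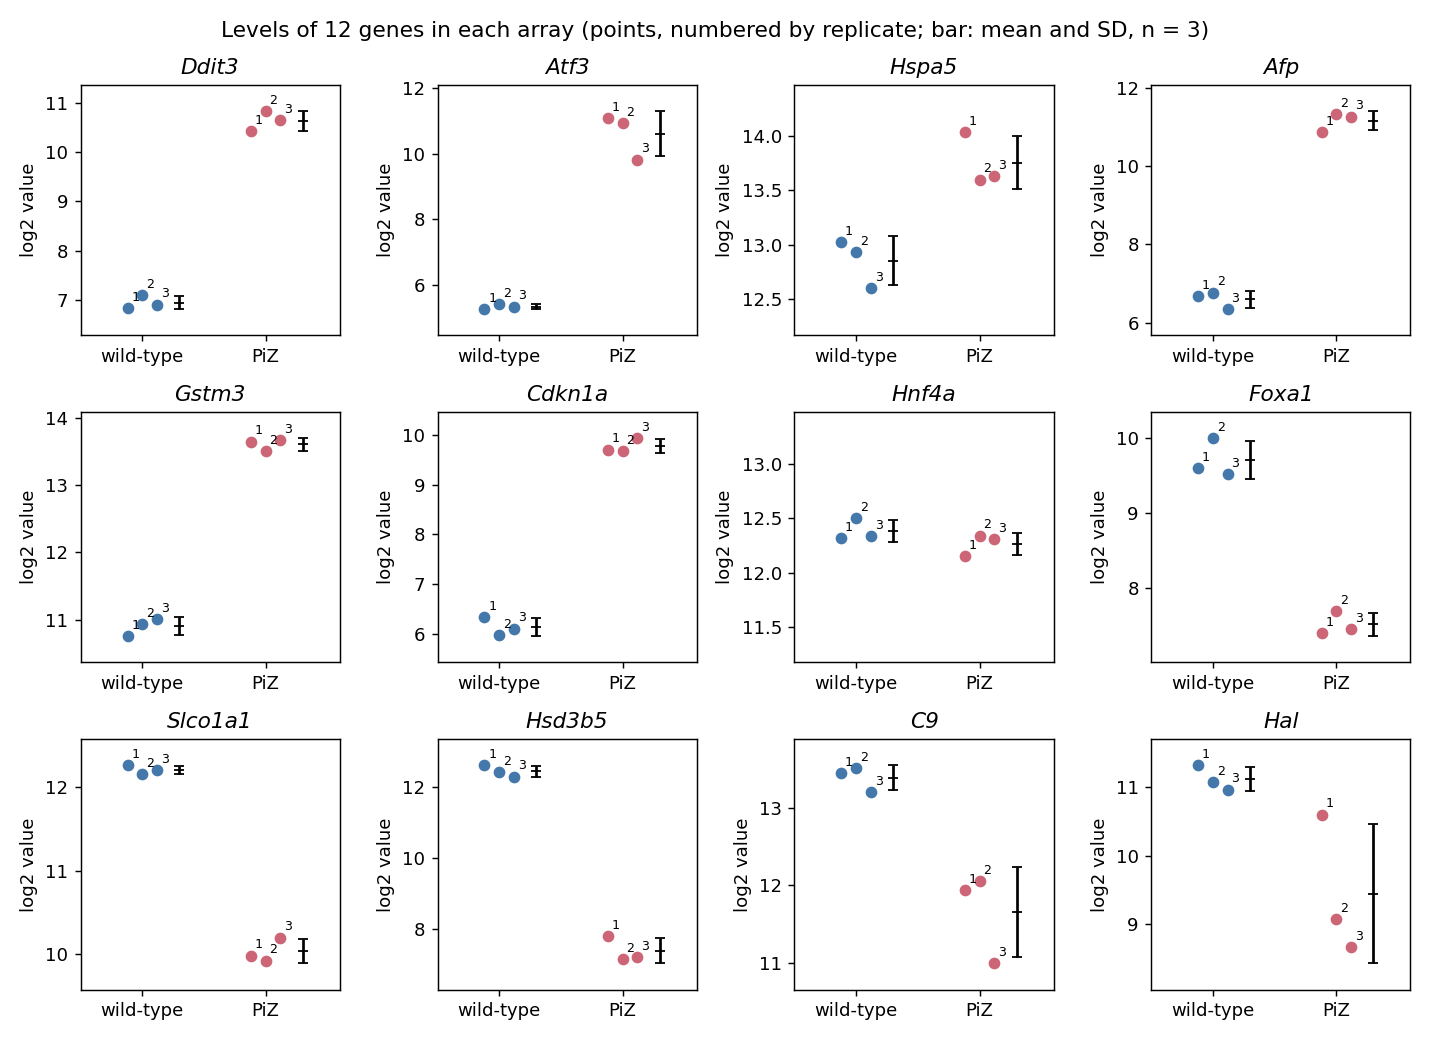
Log2 values of 12 genes in each array, drawn as points numbered by replicate, with wild-type in blue, PiZ in red and a bar for the mean and SD of each group (n = 3). Ddit3 moved from 6.94 to 10.64 and Hsd3b5 from 12.43 to 7.40 with little spread within groups, Hnf4a stayed at 12.38 and 12.26, and Hal read 10.6, 9.07 and 8.67 in PiZ replicates 1, 2 and 3.

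Across all genes, 2921 of 12393 (23.6%) changed at an adjusted p below 0.05, 1396 higher and 1525 lower in PiZ, of which 314 were higher and 450 lower by at least 2-fold. Centring the arrays on reference genes gave 689 higher and 1711 lower genes, so that 28.7% of changed genes were higher, against 47.8% in the main comparison. The groups did not overlap for 5550 genes (44.8%, where chance gives 10%). Against the 3 wild-type arrays, PiZ replicate 1 alone gave 2309 changed genes, 1680 of them among the 2921, under the assumption that it varies like wild-type. Leaving it out gave 6175 changed genes. Leaving out PiZ replicate 2 or 3 gave 1787 or 1442, and leaving out wild-type replicate 1, 2 or 3 gave 1105, 1262 or 1068.

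Of 37 gene lists tested with camera, which sets a list against all other genes, 19 passed, 9 higher and 10 lower in PiZ. None of the 19 passed when camera estimated the correlation between genes, where 4 of the 37 lists had an unadjusted p below 0.05, and 21 lists passed with fry. Pericentral (fry adjusted p = 0.00323), NF-kB (0.033), xenobiotic (0.0123), interferon (0.00243), macrophage (0.0405) and erythroid genes (0.00243) passed with fry and not with camera. In PiZ replicate 1 alone 20 lists passed, 15 of them among the 19, and the other 5 were cholesterol synthesis, xenobiotic metabolism, proliferation, macrophage and female-biased genes, all higher. The lists were fixed before the data were examined.

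**Figure D3:**
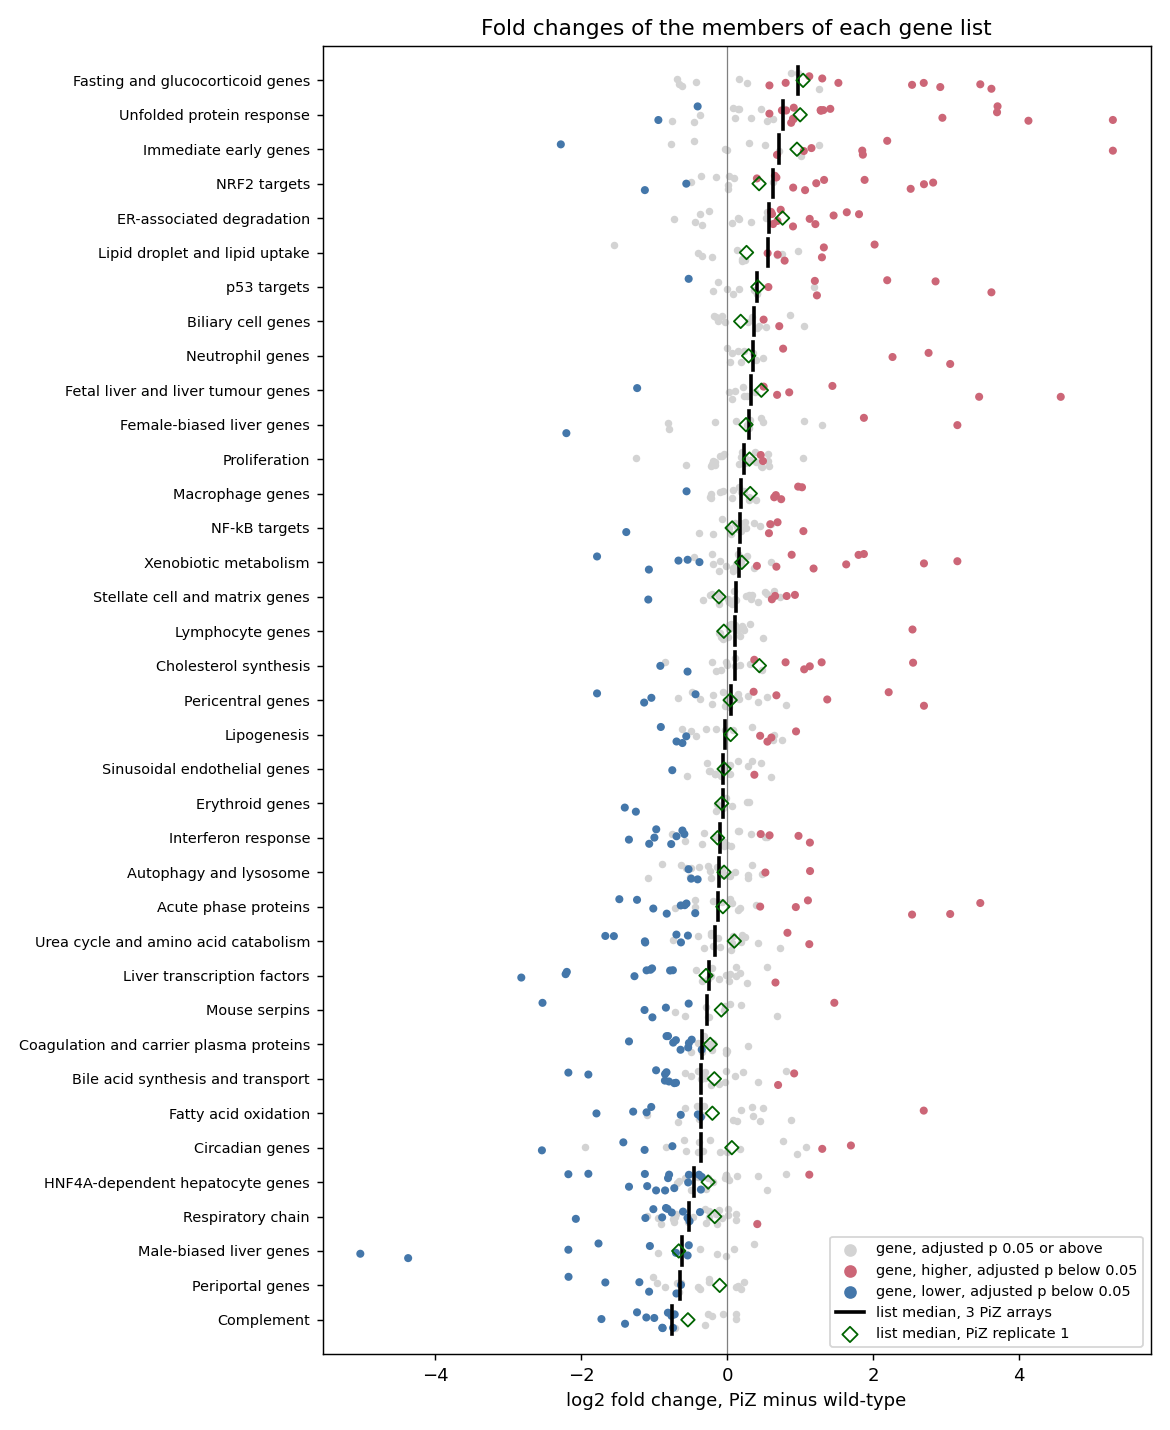
Log2 fold changes (PiZ minus wild-type, horizontal axis) of the members of the 37 tested lists, 1 point per gene, red where higher and blue where lower at an adjusted p below 0.05, and grey otherwise. Black bars mark the median over the 3 PiZ arrays, from -0.75 for complement to 0.97 for fasting and glucocorticoid genes, and green diamonds mark the median in PiZ replicate 1.

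HNF4A-dependent hepatocyte genes were lower in PiZ liver as a list, while Hnf4a itself did not pass the test. The organic anion transporter Slco1a1 fell by 2.18 (SE 0.12, limma adjusted p = 7.15e-05), the bile salt importer Slc10a1 (Ntcp) by 1.90 (SE 0.31), coagulation factor F11 by 1.35 (SE 0.14) and the urea cycle enzyme Otc by 1.13 (SE 0.24). Of 34 measured members, 1 rose and 15 fell (2 and 18 adjusted over the list alone), and the median was -0.45. The list stood below other genes with a camera adjusted p = 1.32e-05, and with adjusted p = 0.351 with an estimated correlation. Its median was -0.26 in PiZ replicate 1 and -0.45 in replicates 2 and 3, and its mean of -0.45 shrank to -0.22 in PiZ replicate 1 alone and to -0.21 with the 3′ to 5′ difference as a covariate. Hnf4a differed by -0.12 (SE 0.11, adjusted p = 0.456) in its brightest probe set, and by 0.0067 after cyclic loess. Another of its 4 probe sets fell by 0.64 (adjusted p = 0.0118 over all probe sets), and the remaining ones read -0.49 and -0.05.

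Several partners of Hnf4a in the hepatocyte transcription factor network fell. Besides Hhex, Foxa1 fell by 2.20 (SE 0.16, limma adjusted p = 0.00028), Onecut1 (HNF6) by 2.21 (SE 0.55), Foxa2 by 1.27 (SE 0.21) and Cebpa by 0.78 (SE 0.13). Of 24 measured liver transcription factors, 1 rose and 9 fell, also when adjusted over the list alone (median -0.24, camera adjusted p = 0.00278, and adjusted p = 0.287 with an estimated correlation). The median was -0.29 in PiZ replicate 1 and -0.26 in replicates 2 and 3. The call was lost without dim genes (adjusted p = 0.0594).

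Among zonated genes, those of the periportal side were lower as a list and those of the pericentral side moved both ways. Periportal Hsd17b6, a steroid and retinol dehydrogenase, fell by 2.17 (SE 0.51), histidine ammonia-lyase Hal by 1.67 (SE 0.44), the immunoglobulin receptor Pigr by 1.20 (SE 0.32) and the growth factor gene Igf1 by 1.07 (SE 0.16). Of 20 measured periportal genes, 0 rose and 6 fell, also when adjusted over the list alone (median -0.65, camera adjusted p = 0.000621, and adjusted p = 0.51 with an estimated correlation). Cps1 (-0.40, SE 0.16), Pck1 (-0.66, SE 0.29) and Cyp2f2 (-0.97, SE 0.36), classical periportal genes, did not pass, and Ass1 was not named by a single-gene probe set here. Pck1 read 12.5, 11.5 and 11.3 in PiZ replicates 1, 2 and 3 (wild-type mean 12.4), and Cyp2f2 13.5, 12.2 and 11.9 (13.5). Cps1, Pck1 and Cyp2f2 passed in 2, 3 and 4 of 18 alternative fits. The periportal median was -0.10 in PiZ replicate 1 and -0.77 in replicates 2 and 3. In PiZ replicate 1 alone the list did not pass (adjusted p = 0.12), nor with the 3′ to 5′ difference as a covariate (adjusted p = 0.273) or with fry (adjusted p = 0.0702). The 2 probe sets of Hsd17b6 read -2.17 and 0.57.

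Pericentral glutathione transferase Gstm3 rose by 2.70 (SE 0.12, limma adjusted p = 2.51e-05), the ammonia transporter Rhbg by 2.21 (SE 0.15) and the dicarboxylate transporter Slc13a3 by 1.37 (SE 0.23), while the cytochrome Cyp2c37 fell by 1.78 (SE 0.25). Of 27 measured pericentral genes, 5 rose and 4 fell (6 and 5 adjusted over the list alone), with a median of 0.05 and a camera adjusted p = 0.95. The median was 0.04 in PiZ replicate 1 and 0.05 in replicates 2 and 3. Glutamine synthetase Glul, the marker of the innermost pericentral cells, read -0.06 (SE 0.13), and 0.06 after cyclic loess and 0.01 after a further quantile normalization. Cyp2e1 (-0.21, SE 0.10), Cyp1a2 (0.15, SE 0.13) and the Wnt target Axin2 (0.29, SE 0.24) did not pass either.

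Genes of the unfolded protein response were higher as a list. Of 30 measured members, 16 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.77, a camera adjusted p = 1.33e-05, and adjusted p = 0.351 with an estimated correlation. Besides Atf3, Trib3, Asns and Ddit3, the ER chaperone Hspa5 (BiP) rose by 0.90 (SE 0.17, limma adjusted p = 0.0103). Xbp1, whose spliced mRNA makes a factor of the same response, fell by 0.40 (SE 0.12, adjusted p = 0.048) in its brightest probe set, and its 4 probe sets ran from -1.85 to 0.36. Genes of ER-associated degradation, which clears misfolded proteins, were higher as a list too. The derlin Derl3 rose by 1.81 (SE 0.22), Ubxn4 by 1.64 (SE 0.14), the ubiquitin ligase Syvn1 (Hrd1) by 1.46 (SE 0.13) and the mannosidase-like Edem2 by 1.21 (SE 0.11). Of 22 measured, 11 rose and 0 fell (12 and 1 adjusted over the list alone; median 0.58, camera adjusted p = 0.00283, and adjusted p = 0.45 with an estimated correlation). Both lists stood higher in PiZ replicate 1 (medians 1.00 and 0.76) than in replicates 2 and 3 (0.53 and 0.53), and without PiZ replicate 1 degradation genes did not pass (adjusted p = 0.112).

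NRF2 target genes and p53 target genes were higher as lists. Among NRF2 targets, the glutathione transferase Gsta2 rose by 2.82 (SE 0.16), the sulfiredoxin Srxn1 by 2.51 (SE 0.10) and the quinone reductase Nqo1 by 1.88 (SE 0.12). Of 21 measured, 11 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.63, camera adjusted p = 0.00283, and adjusted p = 0.287 with an estimated correlation), with medians of 0.44 in PiZ replicate 1 and 0.46 in replicates 2 and 3. Among p53 targets, the cell cycle inhibitor Cdkn1a (p21) rose by 3.62 (SE 0.14), Trp53inp1 by 2.86 (SE 0.18), Btg2 by 2.19 (SE 0.48) and the kinase gene Plk3 by 1.23 (SE 0.24). Of 16 measured, 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.00942, and adjusted p = 0.287 with an estimated correlation). Their medians were 0.42 in both sets of PiZ arrays, and without PiZ replicate 1 the list did not pass (adjusted p = 0.0626).

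Autophagy and NF-kB genes did not pass as lists with camera. The autophagy receptor Sqstm1 (p62) rose by 1.14 (SE 0.17, limma adjusted p = 0.00492) and the lysosomal protease Ctsd by 0.52 (SE 0.15), while the sialidase Neu1 fell by 0.53 (SE 0.10) and Uvrag by 0.49 (SE 0.12). Of 28 measured autophagy and lysosome genes, 2 rose and 3 fell (1 and 3 adjusted over the list alone; median -0.12, camera adjusted p = 0.112). The probe sets of Neu1 ran from -0.53 to 0.31. Among NF-kB targets Bcl3 rose by 1.04 (SE 0.13), the adhesion molecule Vcam1 by 0.69 (SE 0.19) and Relb by 0.59 (SE 0.16), and the chemokine Cxcl1 fell by 1.38 (SE 0.39). Of 21 measured, 4 rose and 1 fell, also when adjusted over the list alone (median 0.18, camera adjusted p = 0.126). The 3 probe sets of Vcam1 ran from -0.19 to 0.69. The medians of the autophagy and NF-kB lists were -0.04 and 0.07 in PiZ replicate 1, and -0.20 and 0.24 in replicates 2 and 3.

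Complement genes and genes of coagulation and carrier proteins were lower in PiZ liver as lists. The terminal complement component C9 fell by 1.72 (SE 0.27), the C1 proteases C1s1 by 1.40 (SE 0.14) and C1ra by 1.11 (SE 0.16), and factor B, Cfb, by 1.24 (SE 0.22). Of 18 measured complement genes, 0 rose and 11 fell (0 and 14 adjusted over the list alone), with a median of -0.75, a camera adjusted p = 1.29e-06, and adjusted p = 0.287 with an estimated correlation. Coagulation factor F5 fell by 0.83 (SE 0.12), apolipoprotein Apob by 0.81 (SE 0.18) and plasminogen Plg by 0.74 (SE 0.17). Of 24 measured coagulation and carrier proteins, 0 rose and 10 fell (1 and 15 adjusted over the list alone; median -0.35, camera adjusted p = 1.14e-05, and adjusted p = 0.351 with an estimated correlation). In PiZ replicate 1 the medians of complement and of coagulation and carrier genes were -0.54 and -0.23, and in replicates 2 and 3 they were -0.87 and -0.44.

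Mouse serpins were lower as a list, a call that several alternatives ended, and acute phase genes went both ways. Besides Serpina12, the C1 inhibitor Serping1 fell by 1.13 (SE 0.18) and heparin cofactor Serpind1 by 1.02 (SE 0.28), while the intracellular Serpinb6a rose by 1.47 (SE 0.21). Of 16 measured mouse serpins, 1 rose and 5 fell, also when adjusted over the list alone (median -0.28, camera adjusted p = 0.0172, and adjusted p = 0.51 with an estimated correlation). The serpin median was -0.08 in PiZ replicate 1 and -0.32 in replicates 2 and 3. The serpin list did not pass in PiZ replicate 1 alone (adjusted p = 0.377), with the 3′ to 5′ difference as a covariate (adjusted p = 0.378), without dim genes (adjusted p = 0.163), after cyclic loess (adjusted p = 0.0701) or with fry (adjusted p = 0.0702). Among acute phase genes the metallothioneins Mt2 and Mt1 rose by 3.47 (SE 0.65) and 2.53 (SE 0.45) and lipocalin Lcn2 by 3.06 (SE 0.18), and the metalloreductase Steap4 fell by 1.48 (SE 0.18). Of 25 measured, 6 rose and 8 fell (6 and 9 adjusted over the list alone), and the median of -0.12 and the mean of 0.15 differed in sign (camera adjusted p = 0.235). Their median was -0.06 in PiZ replicate 1 and -0.12 in replicates 2 and 3.

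Bile acid genes were lower as a list. Besides Slco1a1 and Slc10a1, the bile acid conjugating enzyme Slc27a5 fell by 0.97 (SE 0.21) and the 12-alpha-hydroxylase Cyp8b1 by 0.85 (SE 0.12, limma adjusted p = 0.00437), while the canalicular exporter Abcc2 rose by 0.92 (SE 0.17). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.80 (SE 0.56) and did not pass. Of 26 measured, 2 rose and 9 fell (3 and 9 adjusted over the list alone; median -0.36, camera adjusted p = 0.00278, and adjusted p = 0.287 with an estimated correlation). The median was -0.18 in PiZ replicate 1 and -0.41 in replicates 2 and 3, and the list did not pass without dim genes (adjusted p = 0.0714). In the urea cycle and amino acid list, Hal, Otc and the mitochondrial aspartate carrier Slc25a13 (-1.55, SE 0.39) fell and tyrosine aminotransferase Tat rose by 1.12 (SE 0.27). Of 26 measured, 2 rose and 7 fell, also when adjusted over the list alone (median -0.16, camera adjusted p = 0.12). That median was 0.10 in PiZ replicate 1 and -0.35 in replicates 2 and 3.

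Genes of the respiratory chain and of fatty acid oxidation were lower as lists, with lower medians in the PiZ arrays of larger 3′ to 5′ difference. Of the respiratory chain, the succinate dehydrogenase subunit Sdhd fell by 2.07 (SE 0.61) in its brightest probe set, and by 0.50 in the other. The brightest probe set read 10.9, 8.32 and 8.52 in PiZ replicates 1, 2 and 3 (wild-type mean 11.3). The ATP synthase subunit Atp5o fell by 1.12 (SE 0.25), the Rieske protein Uqcrfs1 by 1.01 (SE 0.27) and Ndufa9 of complex I by 0.89 (SE 0.19). Of 34 measured, 1 rose and 11 fell (1 and 19 adjusted over the list alone; median -0.53, camera adjusted p = 1.32e-05, and adjusted p = 0.421 with an estimated correlation). The median was -0.17 in PiZ replicate 1 and -0.67 in replicates 2 and 3. In fatty acid oxidation, the electron carrier Etfdh fell by 1.79 (SE 0.42), and the carnitine transferase Cpt1a (-1.29, SE 0.16) and the regulator Ppara (-1.10, SE 0.21) fell too, while the pyruvate dehydrogenase kinase Pdk4 rose by 2.69 (SE 0.40). Of 23 measured, 1 rose and 7 fell (2 and 9 adjusted over the list alone; median -0.36, camera adjusted p = 0.0222, and adjusted p = 0.51 with an estimated correlation). The medians were -0.20 and -0.46, and the list did not pass in PiZ replicate 1 alone (adjusted p = 0.0767), after cyclic loess (adjusted p = 0.104), after a further quantile normalization (adjusted p = 0.0679), without dim genes (adjusted p = 0.184), with the 3′ to 5′ difference as a covariate (adjusted p = 0.151), with fry (adjusted p = 0.0535) or without wild-type replicate 3 (adjusted p = 0.055).

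Lipid droplet and uptake genes were higher as a list, and lipid synthesis genes did not pass as lists. The fatty acid transporter Cd36 rose by 2.02 (SE 0.12, limma adjusted p = 0.000114), Lpin2 by 1.32 (SE 0.20), the lipoprotein receptor Vldlr by 1.30 (SE 0.14) and Mogat1 by 0.79 (SE 0.19). Of 17 measured lipid droplet and uptake genes, 6 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.55, camera adjusted p = 0.0231, and adjusted p = 0.351 with an estimated correlation). Their median was 0.27 in PiZ replicate 1, where the list alone did not pass (adjusted p = 0.0819), and 0.48 in replicates 2 and 3, and the call was also lost with the 3′ to 5′ difference as a covariate (adjusted p = 0.053). In cholesterol synthesis Mvd rose by 2.55 (SE 0.28), Hmgcs1 by 1.29 (SE 0.23), Fdft1 by 1.13 (SE 0.18) and Lss by 1.05 (SE 0.23). Of 19 measured, 6 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.283), with medians of 0.44 in PiZ replicate 1 and 0.07 in replicates 2 and 3. In lipogenesis Acacb rose by 0.94 (SE 0.23), and the pyruvate kinase Pklr fell by 0.91 (SE 0.26) and the desaturases Fads1 and Fads2 by 0.69 (SE 0.19) and 0.61 (SE 0.16). Of 19 measured, 4 rose and 4 fell (6 and 5 adjusted over the list alone). The lipogenesis median of -0.03 and mean of 0.01 differed in sign (camera adjusted p = 0.778), with medians of 0.05 and -0.13 in PiZ replicate 1 and in replicates 2 and 3.

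Genes of xenobiotic metabolism moved both ways. The cytochromes Cyp2b9 and Cyp2b13 rose by 3.15 (SE 0.21) and 1.87 (SE 0.29) and the glutathione transferase Gstm2 by 1.80 (SE 0.15), while Cyp2c37 fell. Of 30 measured, 9 rose and 5 fell, also when adjusted over the list alone (median 0.16, camera adjusted p = 0.15), with medians of 0.20 in PiZ replicate 1 and 0.18 in replicates 2 and 3. Among genes of fetal liver and liver tumours, besides Afp, the surface protein gene Ly6d rose by 3.45 (SE 0.22) and S100a10 by 1.44 (SE 0.16), and the trefoil factor Tff3 fell by 1.23 (SE 0.23). Of 14 measured, 6 rose and 1 fell, also when adjusted over the list alone (median 0.33, camera adjusted p = 0.00769, and adjusted p = 0.351 with an estimated correlation). Their medians were 0.47 and 0.41, and the call was lost with array quality weights (adjusted p = 0.0525). Of 26 proliferation genes, the replication helicase subunit Mcm2 (0.49, SE 0.13) and thymidylate synthase Tyms (0.46, SE 0.12) rose and 0 fell (0 and 0 adjusted over the list alone; median 0.22, camera adjusted p = 0.183). The proliferation medians were 0.31 in PiZ replicate 1 and 0.18 in replicates 2 and 3.

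Neutrophil genes were higher as a list, although no more than 2 of 13 were as bright as the median gene, whereas the lists of other non-hepatocyte cells did not pass with camera. The calprotectin genes S100a8 and S100a9 rose by 2.76 (SE 0.25) and 2.27 (SE 0.25), Mmp8 by 0.77 (SE 0.13), and Lcn2, which the acute phase list also holds, is on this list too. Of 13 measured neutrophil genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.36, camera adjusted p = 0.0022, and adjusted p = 0.287 with an estimated correlation), with medians of 0.29 in PiZ replicate 1 and 0.39 in replicates 2 and 3. Among macrophage genes Cd14 (1.02, SE 0.21), Marco (0.97, SE 0.16), Slc15a3 (0.74, SE 0.11) and Cd5l (0.67, SE 0.12) rose. Of 19 measured, 5 rose and 1 fell, also when adjusted over the list alone (median 0.18, camera adjusted p = 0.138), with medians of 0.32 and 0.27. The immunoglobulin heavy chain gene Ighm rose by 2.53 (SE 0.41) as the 1 member called among 17 lymphocyte genes, also when adjusted over the list alone (median 0.11, camera adjusted p = 0.372). Its 11 probe sets ran from -0.22 to 2.53, and the list medians were -0.05 and 0.16. Carbonic anhydrase Car1 (-1.40, SE 0.13) and the factor Klf1 (-1.25, SE 0.14) fell among 9 erythroid genes, where 0 rose, also when adjusted over the list alone (median -0.06, camera adjusted p = 0.15), with medians of -0.08 and -0.09.

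Genes of stellate, biliary and endothelial cells showed few calls. Among stellate cell and matrix genes Rgs5 (0.93, SE 0.12), the fibulin Fbln2 (0.82, SE 0.18) and the collagen Col4a1 (0.66, SE 0.14) rose and the proteoglycan Lum fell by 1.08 (SE 0.21). Of 27 measured, 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.201), with medians of -0.11 in PiZ replicate 1 and 0.27 in replicates 2 and 3. Among 14 biliary cell genes, Muc1 (0.71, SE 0.17) and Tspan8 (0.50, SE 0.15) rose and 0 fell (5 and 0 adjusted over the list alone; median 0.37, camera adjusted p = 0.126), with medians of 0.19 and 0.43. Among 19 sinusoidal endothelial genes, the receptor gene Flt4 rose by 0.37 (SE 0.11) and Gpr182 fell by 0.75 (SE 0.11) (0 and 1 adjusted over the list alone; median -0.05, camera adjusted p = 0.465), with medians of -0.04 and -0.05. In the interferon response, the GTPase Iigp1 (-1.35, SE 0.20), the immunoproteasome subunit Psmb8 (-1.07, SE 0.13) and Ifit1 (-0.998, SE 0.12) fell and Oasl1 rose by 1.13 (SE 0.22). Of 26 measured, 4 rose and 8 fell (6 and 11 adjusted over the list alone; median -0.10, camera adjusted p = 0.0734), with medians of -0.13 and -0.15.

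Male-biased liver genes were lower as a list, to a like extent in PiZ replicate 1 and in replicates 2 and 3. The labels do not give the sex of the mice. Besides Hsd3b5, Ugt2b38 and Slco1a1, the major urinary protein gene Mup3 fell by 1.76 (SE 0.20, limma adjusted p = 0.002), and 8 of 14 measured genes fell and 0 rose (9 and 0 adjusted over the list alone). The median was -0.62 (camera adjusted p = 1.33e-05, and adjusted p = 0.263 with an estimated correlation), at -0.66 in PiZ replicate 1 and -0.63 in replicates 2 and 3. Of 15 female-biased genes, Cyp2b9 and Cyp2b13 rose and the hydroxyacid oxidase Hao2 fell by 2.20 (SE 0.39), the same calls as adjusted over the list alone (2 and 1; median 0.30, camera adjusted p = 0.126), with medians of 0.26 and 0.29.

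Genes that respond to fasting and to handling were higher as lists, and circadian genes moved both ways. The labels give neither feeding state nor time of collection, so these differences cannot be assigned to the genotype. Among fasting and glucocorticoid genes, Igfbp1 rose by 2.92 (SE 0.58), and Cdkn1a, Mt2 and Pdk4 are members as well. Of 19 measured, 10 rose and 0 fell (12 and 1 adjusted over the list alone; median 0.97, camera adjusted p = 0.00477, and adjusted p = 0.287 with an estimated correlation). Its median was 1.04 in PiZ replicate 1 and 0.79 in replicates 2 and 3, and the list did not pass without PiZ replicate 1 (adjusted p = 0.077) or with array quality weights (adjusted p = 0.0633). Of 17 immediate early genes, 7 rose, among them Atf3, Btg2 and Nr4a1 (1.86, SE 0.27), and 1 fell, Socs3 (-2.28, SE 0.36) (8 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 0.025, and adjusted p = 0.525 with an estimated correlation). These medians were 0.96 and 0.55, and this list did not pass without PiZ replicate 1 (adjusted p = 0.138), wild-type replicate 2 (0.0564), wild-type replicate 3 (0.055) or dim genes (0.0774), nor with array quality weights (adjusted p = 0.185) or fry (adjusted p = 0.0581). Among circadian genes Noct (1.70, SE 0.43) and Per1 (1.30, SE 0.30) rose and Dbp and Hlf (-1.42, SE 0.17) fell, and the clock factor Arntl (Bmal1) differed by 0.76 (SE 0.55) without passing. Of 20 measured, 2 rose and 4 fell (4 and 5 adjusted over the list alone; median -0.36, camera adjusted p = 0.126), with medians of 0.06 in PiZ replicate 1 and -0.43 in replicates 2 and 3.

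Genes often used as references moved as well. The transferrin receptor Tfrc rose by 1.44 (SE 0.22) and Ywhaz by 0.90 (SE 0.20), and Gusb fell by 1.18 (SE 0.26) and Tbp by 0.72 (SE 0.14). Of 13 measured reference genes, 6 rose and 3 fell (6 and 4 adjusted over the list alone), with a median of 0.15, at 0.33 in PiZ replicate 1 and 0.00 in replicates 2 and 3. The list served for scaling and was not tested as a set. Its probe sets differed for some genes, from -0.48 to 0.90 for Ywhaz.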

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

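Of 143 changed named genes, 85 passed at an adjusted p below 0.05 in each of the 18 alternative fits that tested them, but 72 of the 85 were tested in all 18 fits, and 70 of these also met an adjusted p below 0.01 and a 1.5-fold minimum in the main comparison. No changed named gene turned its sign in a fit that tested it. For fits that left arrays out this was fixed in advance, since the groups did not overlap for these genes. It is informative only for fits that changed the probe sets, the scaling or the covariates. HNF4A-dependent genes, the unfolded protein response, NRF2 targets, coagulation and carrier proteins, complement, the respiratory chain, neutrophil and male-biased genes (8 of 19 lists) passed under every alternative except those with an estimated correlation, though neutrophil genes had too few members for a test without dim genes. The mean changes of 3 of the 8 shrank by over 1.5 times in PiZ replicate 1 alone and with the 3′ to 5′ covariate, from -0.45 to -0.22 and -0.21 for HNF4A-dependent genes, from -0.50 to -0.18 and -0.17 for the respiratory chain, and from -0.41 to -0.24 and -0.24 for coagulation and carrier genes. Bile acid genes went from -0.38 to -0.25 and -0.23. The fits with PiZ replicate 1 alone, with the 3′ to 5′ covariate and with an estimated correlation without PiZ replicate 1 were chosen after seeing the data. The causes of the changes below were not tested, except where fewer arrays or genes or a stricter threshold set them. Files without detection calls leave signal over background unknown.

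The count of changed genes (2921, with 1396 higher and 1525 lower) ran from 1068 to 6175 when 1 array was left out, with 518 to 3397 higher and 550 to 2778 lower. The lowest values came without wild-type replicate 3 and the highest without PiZ replicate 1. Array quality weights, which gave PiZ replicate 1 a weight of 0.173, called 6520 genes, 3641 higher and 2879 lower. The covariate left 1814, 867 higher and 947 lower, of which 1342 were among the 2921. An adjusted p below 0.01 left 914, 444 higher and 470 lower, and a 1.5-fold minimum left 882 higher. Without dim genes 918 were higher, and with centring on reference genes 689. Whether replicate numbers pair the mice is not known. Deviations of same-numbered arrays correlated at 0.264, 0.285 and -0.034. Wild-type replicates 1 and 2 correlated best with their own number and wild-type replicate 3 did not. With 3 arrays per group this neither shows nor excludes pairing. The replicate block gave 3225 changed genes and 19 lists.

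Camera called 13 to 24 lists under the other gene-level settings and 19 on ranks. With an estimated correlation it called 0 lists (4 at an unadjusted p below 0.05), and without PiZ replicate 1 also 0 (5 at an unadjusted p below 0.05), while fry called 21. With an estimated correlation, mean log2 changes and adjusted p were -0.45 and 0.351 for HNF4A-dependent genes, -0.54 and 0.287 for liver transcription factors and -0.64 and 0.51 for periportal genes. Without PiZ replicate 1 they were -0.57, -0.51 and -0.88, all with adjusted p = 0.293. Transcription factors had a mean of -0.61 without dim genes (adjusted p = 0.0594). Periportal genes had means of -0.18 in PiZ replicate 1 alone (adjusted p = 0.12) and -0.17 with the covariate (0.273), and -0.64 with fry (0.0702). Pericentral genes, with a mean of 0.13, passed only with fry (0.00323). Of the 18 lists that had not passed, 12 passed under at least 1 alternative (pericentral, autophagy, NF-kB, urea cycle, cholesterol synthesis, xenobiotic, proliferation, interferon, biliary, macrophage, erythroid and female-biased genes), and 6 under none that was run (acute phase, lipogenesis, stellate, sinusoidal, lymphocyte and circadian genes).

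Among named genes and lists, reversed signs all belonged to results that had not passed. Among all 2921 changed genes reversals did occur, 34 of them with means over probe sets. Cyclic loess gave 0.0067 for Hnf4a, 0.077 for Serpina1b, 0.060 for Glul and 0.057 for sinusoidal genes, and a further quantile normalization gave 0.069 for Serpina1b, 0.012 for Glul and 0.065 for sinusoidal genes. With each array left out in turn, Glul ran from -0.15 to 0.054 (without PiZ replicate 1), Axin2 from -0.0065 (without PiZ replicate 3) to 0.49, lipogenesis from -0.15 (without wild-type replicate 1) to 0.095, and sinusoidal genes from -0.046 to 0.013 (without wild-type replicate 2). Lipogenesis was also below 0 without PiZ replicate 1 (-0.0023, also under the estimated correlation) and PiZ replicate 3 (-0.019), and sinusoidal genes were above 0 without PiZ replicate 3 (0.0031). PiZ replicate 1 alone gave 0.077 for Pck1, 0.035 for autophagy, 0.18 for urea cycle and -0.036 for stellate genes. The covariate gave 0.062 for Pck1, -0.014 for Cyp1a2, -0.026 for Xist, 0.052 for autophagy, 0.19 for urea cycle and -0.071 for stellate genes. Means over probe sets gave -0.072 for lipogenesis and 0.035 for sinusoidal genes. Leaving out less specific probe sets gave -0.092 for lipogenesis, and centring on reference genes gave -0.040.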

Other observations

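Genes of amino acid synthesis, transport and tRNA charging that respond to the factor ATF4 were higher in PiZ liver. Serine synthesis gene Psat1 rose by 2.73 (SE 0.22), proline synthesis gene Aldh18a1 by 2.25 (SE 0.15), the amino acid transporter subunit Slc3a2 by 1.90 (SE 0.19) and the folate enzyme Mthfd2 by 1.43 (SE 0.18). Of 23 measured genes of this list, 14 rose and 0 fell, also when adjusted over the list alone, with a median of 0.56, at 0.59 in PiZ replicate 1 and 0.67 in replicates 2 and 3. The list was written after the rises of Atf3, Ddit3, Trib3 and Asns had been seen, without those genes and before its own values were seen. Its median lay at percentile 100, the largest possible, of 10000 random lists matched on mean expression. Members of the random lists were drawn one by one, so correlation between genes was ignored, and camera was not run on this list. As a hypothesis, these rises are consistent with an ATF4 response in PiZ liver, while Phgdh (0.11, SE 0.15) and Cth (0.06, SE 0.30) did not pass.

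Tests chosen only after the result was seen were those of the wild-type share needed in PiZ replicate 1, of list means with the 3′ to 5′ covariate, of hepatocyte number and of female livers. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. With limma the real split called 2921 genes and the highest other split 0, although up to 1387 genes had an unadjusted p below 0.05 in another split. Every other split puts arrays of both groups on each side, so the group difference enters the spread that limma tests against. Few gene calls there were thus close to fixed in advance and do not argue against chance. With camera the real split called 19 lists and the others 7 to 14. In both cases 1 of the 10 splits, the real one, gave a result as large.

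PiZ replicate 1 lay between the wild-type arrays and PiZ replicates 2 and 3. Shortened RNA in this array is argued against by its Gapdh 3′ to 5′ difference of 1.99, against up to 4.39 in the others. Wild-type RNA mixed into it would need a share of 46.9%, but 14 abundant wild-type genes lay more than 1 on the log2 scale below what that share would leave, Hsd3b5 at 4.09% and Ugt2b38 at 4.94% of wild-type. Of 1295 genes that differed at least 2-fold, 18.3% (exact 95% interval 16.2 to 20.5) had PiZ replicate 1 at or beyond a group mean, which met neither bound set in advance. The candidate explanations that stay open are RNA quality of PiZ replicates 2 and 3 and time of day. Across 1850 genes with 2 probe sets, the difference of these replicates from replicate 1 correlated between probe sets at 0.239. The difference of replicate 1 from wild-type correlated at 0.868. Circadian genes differed between replicate 1 and replicates 2 and 3 by a median of 0.59, at percentile 99.8 of matched lists. Those lists were matched on mean expression only, and circadian genes can vary among wild-type arrays too (Dbp read 10.9, 11.7 and 12.3). The percentile thus cannot decide for time of day, nor tie it to the position of replicate 1 across all genes.

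Lists of abundant hepatocyte transcripts fell. A compressed signal range in the PiZ arrays is argued against for complement (percentile 0.01 of matched random lists, the smallest possible), respiratory chain (0.02), periportal (0.03), male-biased (0.05) and HNF4A-dependent genes (0.16). Serpins (7.18) and liver transcription factors (8.66) met the bound set in advance for it. Their matched lists, however, had typical medians of only -0.057 and -0.066, against -0.28 and -0.24 for the lists themselves. Bile acid (2.82), fatty acid oxidation (3.2) and coagulation and carrier genes (5) were undecided. Whether a compressed range raised lists of dim genes was not tested. Random members were drawn one by one, so percentiles of this kind ignore that genes of a list vary together and are likely too extreme. RNA quality of PiZ replicates 2 and 3 was tested by the percentile in replicate 1, which rests on 1 array and excludes nothing alone, and by the group effect on list means over all 6 arrays with the 3′ to 5′ covariate. Counting against it as the whole cause, falls were still there for complement (percentile 0.01, the smallest possible; mean -0.535, 95% interval -0.777 to -0.292), male-biased genes (0.01; -1.19, -1.64 to -0.732), liver transcription factors (0.37; -0.585, -0.85 to -0.32) and coagulation and carrier genes (1.05; -0.24, -0.354 to -0.126). The percentiles of these lists and of HNF4A-dependent genes (0.18) met the bound set in advance, but that bound was wrong to stand on 1 array, and the covariate leans on the same one, so RNA quality is not excluded for any list. The mean of HNF4A-dependent genes moved from -0.453 to -0.206, with an interval of -0.42 to 0.00778, and respiratory chain (3.61), fatty acid oxidation (2.85) and bile acid genes (5.9; -0.227, -0.42 to -0.0334) were undecided. RNA quality could account for the falls of periportal (20.5) and serpin genes (27.7). Fewer hepatocytes, with the other cells keeping their proportions, would raise genes of every other cell type alike. A gain of particular cells, such as neutrophils, need not raise sinusoidal genes, so it stays open. The first form, as the whole cause, is argued against by sinusoidal genes, with 18 of 19 not dim. Their upper quartile of 0.216 lay below the 0.449 taken as needed (the median fall of HNF4A-dependent genes). In PiZ replicate 1 the margin was small, 0.229 against 0.261, and stellate genes (0.208) lay below but macrophage (0.503), biliary (0.444) and neutrophil genes (0.605) above. Over all PiZ arrays, upper quartiles of stellate (0.533) and macrophage genes (0.517) lay above 0.449, and below it over members that were not dim (0.401 of 18 and 0.292 of 13). Biliary (0.522) and neutrophil genes (0.766) lay above it and lymphocyte (0.217) and erythroid genes (0.064) below, but these 4 lists were mostly dim (2 of 14, 2 of 13, 1 of 17 and 2 of 9 were not) and decide nothing. For all 10 lists, RNA quality (Gapdh 3′ to 5′ difference 1.73 higher in PiZ) cannot be told apart from genotype, because replicate 1 is the only PiZ array near wild-type, and an effect of the transgene stays an open hypothesis.

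Male-biased liver genes fell, at a median of -0.66 in PiZ replicate 1 and -0.63 in replicates 2 and 3. Female livers among the PiZ samples are argued against by Y-linked Eif2s3y, which differed by -0.232. Lower growth hormone signalling is a hypothesis that was tested on 4 genes induced by the hormone, from a list of 5 written after the falls had been seen, of which Igf1 was left out later because its fall was already known. Their median of -0.69 lay at percentile 3.52 of matched random lists, which met neither bound set in advance, so the hypothesis stays open. Igfals (-1.34, SE 0.12) and Ghr (-1.06, SE 0.17) fell, while Egfr (-0.31, SE 0.28) and Gadd45g (0.46, SE 0.52) did not pass. An effect of the genotype by another route, and feeding state, which the labels do not give, stay open and untested.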
